A study of Lactococcus lactis subsp. lactis with 6 samples.

How the data were processed

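Total RNA of Lactococcus lactis subsp. lactis strain CHCC2862, from an industrial culture collection, was measured on 6 two-colour microarrays. Per the labels, cultures in M17 broth with 0.5% lactose were grown without shaking (static), shaken at 170 rpm (aerobic), or shaken at 170 rpm with 5 mg/L hemin (respiratory), and were harvested at an OD600 of 1. The labels of the respiratory cultures in both respiratory/static arrays leave out the name of the sugar. Inocula were static stationary cultures. RNA was fixed at harvest, extracted with a column kit, copied into cDNA with random primers and coupled to Cy3 or Cy5, per the labels' protocols. Each array compared 2 of the 3 conditions, so that the 3 conditions form a closed loop. Every comparison has 2 arrays, of which the titles mark the second as a repeat. The first 3 arrays are called the first set here, and the 3 arrays marked as repeats the Repl set. The test condition carried Cy5 in both aerobic/static and both respiratory/static arrays. The 2 respiratory/aerobic arrays hold opposite dye orientations, so only that comparison is dye-balanced. The labels do not say whether the repeat arrays came from new cultures. All p-values therefore measure only the spread between these arrays, which may be technical.

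The values were the authors' processed log ratios of Cy5 over Cy3, 1 per gene and array, deposited as a table of 2101 gene symbols. The deposited values were used unchanged and taken as log2, and how the authors made them from scanned images is not given in the sources used here. The base of the log is not stated in the sources used here. The direction was taken from the titles and dyes in the labels. Base 10 was set aside because the lowest deposited value, -7.54, would then be a ratio beyond a scanner's range, and base 2 was taken, and a natural log was not excluded. Background correction, normalization, the treatment of replicate spots and the reason for blank values are not given in the sources used here. Single-channel intensities were not in the deposited table, so neither signal over background nor an intensity-dependent trend was examined. The deposited medians of the 6 arrays lay between -0.065 and 0.058, so values were used without further centring, by a rule set beforehand that allowed 0.1. Gene symbols are those of the deposited table. A reference table of another L. lactis strain was not used, and no coordinates are given.

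The swapped respiratory/aerobic array was multiplied by -1 by its title. Across 1754 genes its correlation with the other respiratory/aerobic array was -0.68 as deposited and 0.68 after turning. Turned, it correlated at 0.84 with the difference between the mean respiratory/static and mean aerobic/static arrays, and the unswapped array correlated at 0.86 with that difference. Genes are not independent replicates, so no p-value belongs to these correlations. Genes measured on at least 4 arrays, with each comparison represented, were tested, which kept 1792 genes, 1651 of them measured on all 6 arrays, and left 309 untested. No gene symbol had more than 1 row.

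All 6 arrays entered a single limma model (limma 3.58.1 in R 4.3.3) with 2 coefficients, aerobic minus static and respiratory minus static, from which respiratory minus aerobic follows. Each contrast was fitted as a coefficient of its own, so that genes with blanks were estimated exactly. A change is written as the fitted log2 difference ± its standard error from this model. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 in limma's moderated two-sided test, adjusted over the 1792 genes within a comparison. The verbs rose and fell are kept for genes that passed. The model also gave a test of loop closure, which asks whether the direct and the indirect estimates of a comparison differ, and a test of a gene-specific dye effect. Beside the correlation of both effects against static, 100 simulated data sets with no effect and independent arrays were fitted in the same way, because all 6 arrays enter both fitted effects.

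Lists of genes were fixed before the data were examined, 24 in all, and matched by symbol. They covered the heme efflux operon, the respiratory chain with menaquinone and heme maturation, metal transport, oxidative stress, pyruvate metabolism, glycolysis with phosphotransferase (PTS) genes, lactose and galactose use, other carbohydrates, the arginine deiminase pathway, arginine and glutamate metabolism, other amino acid biosynthesis (most of its branched-chain and histidine genes were not tested), peptide use, purines, pyrimidines, ribonucleotide reductases, chaperones, fatty acids, ATP synthase, cell envelope, competence, ribosomal proteins, prophages, transposases and translation factors. Lists with at least 5 members were tested with camera in limma, with a preset correlation of 0.01, over the 1651 genes measured on every array, and adjusted over the lists of a comparison. The estimated correlation of camera and the fry test were run beside it on the same genes. Counts given for a list can therefore cover more genes than its set tests. These tests held 13 of 19 purine, 55 of 76 prophage, 48 of 53 ribosomal protein and 37 of 42 other carbohydrate genes. They held 11 of 13 arginine and glutamate and 38 of 42 other amino acid genes, with smaller gaps in other lists. With an estimated correlation the test rests on the 4 residual degrees of freedom of the model. A call lost there therefore does not show that the list was unchanged. The question of camera is whether a list differs from the other genes, and that of fry is whether it changed at all. The result of 1 short list is not reported here.

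The genes named were taken from those set by a rule written beforehand, and not every gene of the rule is written out. For each comparison it takes the 10 highest and the 10 lowest changes among genes that passed and had the same sign on both of that comparison's own arrays. It adds up to 4 members with the smallest p of each list that passed its set test or had at least 3 members past the threshold, and 14 genes of heme, oxygen and fermentation metabolism in every comparison. Transposase genes were counted and not named. A gene named outside the rule is marked as chosen after its values were seen.

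The model was tested on simulated log ratios of 1792 genes with 200 changed genes. For aerobic against static it recovered 96.0% of 2-fold and 99.9% of 4-fold changes, with 5.27% of calls false. For respiratory against aerobic these values were 96.5%, 100% and 4.70%. The simulated arrays were independent, with no dye effect and no deviation shared by the arrays of a set. These shares may therefore not hold for the measured arrays. Respiratory against static was simulated without changed genes, so its recovery was not tested. Alternatives set before the data were examined were a gene-specific dye term, each comparison's own arrays alone, the first and the Repl set treated as 2 sets of shared cultures, the other sign for the swapped array, median centring, equal spread, quantile normalization, only genes on all 6 arrays, robust eBayes, a 2-fold minimum, leaving out each array in turn, and, for the lists, an estimated correlation and fry. Fits of 1 set alone, a set test on all genes tested and the set tests under each scaling were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.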

Results

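Gene expression of L. lactis subsp. lactis CHCC2862 was compared between static, aerobic and respiratory growth in 6 two-colour arrays, with 2 arrays for each of the 3 comparisons. L. lactis is a fermenting bacterium that lacks heme synthesis, and shaken cultures respire only when heme is supplied. The comparisons ask what shaking changes without heme, what shaking and hemin change together, and what hemin changes in shaken cultures. The aerobic/static arrays measured 1963 and 1855 of 2101 genes, the respiratory/static arrays 1843 and 1754, and the respiratory/aerobic arrays 1995 and 1804. The number of arrays limits the precision. The median standard deviation of a gene between the 2 arrays of a comparison was 0.213 for aerobic/static, 0.210 for respiratory/static and 0.243 for respiratory/aerobic on the log2 scale. The median standard error of a fitted change was 0.158 in aerobic against static and 0.159 in both other comparisons. The base of the deposited logs was taken as 2 and is not given in the sources used here, so every fold rests on it. Across genes, the paired arrays correlated at 0.84, 0.80 and 0.68 respectively.

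Shaken cultures without hemin had higher expression of oxygen defence genes and lower expression of purine synthesis and translation genes than static cultures. The set calls behind this were lost with an estimated correlation (adjusted p = 0.589 with an estimated correlation), and those of purine and translation factor genes also ended in other alternatives given below. noxE, the water-forming NADH oxidase, rose by 3.58 ± 0.15 (log2, 12.0-fold), and sodA, the superoxide dismutase, by 2.59 ± 0.20. adhE, the alcohol-acetaldehyde dehydrogenase, fell by 4.31 ± 0.24 (19.8-fold), and pfl, the pyruvate formate-lyase, fell by 2.34 ± 0.23. Of 1792 genes tested, 1083 passed, 514 of them higher and 569 lower in aerobic cultures. Of these, 229 were at least 2-fold higher and 240 at least 2-fold lower.

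Of 19 tested genes of oxidative stress and thiol redox, 14 rose and 1 fell, with a median change of 2.05 (camera adjusted p = 0.000413, adjusted p = 0.589 with an estimated correlation). Adjusted over the list alone, 14 were higher and 2 lower. pmsX, a peptide methionine sulfoxide reductase, rose by 3.04 ± 0.20, and osmC, of a family of organic peroxide reductases, by 3.49 ± 0.26. The respiratory chain list holds cytochrome bd, NADH dehydrogenase and menaquinone genes, with hemH, hemK and hemN placed there by symbol. Whether hemK acts in heme metabolism was not examined. In this list 9 of 17 rose, hemK (0.60 ± 0.12) among them, and 1 fell. The counts were the same adjusted over the list alone (camera adjusted p = 0.0244, adjusted p = 0.589 with an estimated correlation). The call ended with a set test on all genes tested (adjusted p = 0.0623). The members that rose most clearly were menE (1.11 ± 0.13) and menB (1.19 ± 0.15) of menaquinone synthesis and noxA (1.91 ± 0.29), an NADH dehydrogenase. cydA and cydB, the 2 subunits of cytochrome bd oxidase, changed by 0.08 ± 0.15 and 0.10 ± 0.13 and did not pass (adjusted p = 0.65 and 0.52). hemH, ferrochelatase, changed by 0.23 ± 0.16 (adjusted p = 0.24). The genes ygfC, ygfB and ygfA of the heme efflux operon changed by -0.04 ± 0.16, 0.41 ± 0.22 and 0.23 ± 0.45, and none passed, over all genes or adjusted over the list alone.

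Pyruvate metabolism moved both ways. Of 21 genes, 11 rose and 5 fell, over all genes and adjusted over the list alone, and the set as a whole did not pass (camera adjusted p = 0.0901). Besides the fall of adhE and pfl, genes of acetoin formation rose: als, acetolactate synthase, by 1.72 ± 0.22, aldB by 1.65 ± 0.15 and aldC by 2.53 ± 0.18, both acetolactate decarboxylases. pdhD of the pyruvate dehydrogenase complex rose by 1.79 ± 0.20, and nifJ, a pyruvate-flavodoxin oxidoreductase outside the list, fell by 3.84 ± 0.20. ldh, lactate dehydrogenase, changed by -0.20 ± 0.17 and did not pass (adjusted p = 0.33). Of 24 glycolysis and PTS genes, 2 rose and 8 fell, also adjusted over the list alone, and the set did not pass (camera adjusted p = 0.0901). Of the mannose PTS, ptnAB (-2.09 ± 0.19) and ptnC (-2.26 ± 0.22) fell. Of 42 other carbohydrate genes, 10 rose and 16 fell, also adjusted over the list alone (camera adjusted p = 0.264), with amyL, an alpha-amylase, at 2.41 ± 0.17 and glpF1, a glycerol facilitator, at -1.57 ± 0.16. With fry, which tests against no change, the pyruvate, glycolysis and other carbohydrate lists passed (adjusted p = 0.00721, 0.0188 and 0.00907).

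Genes of arginine breakdown fell. In the arginine deiminase list 7 of 11 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0474, adjusted p = 0.589 with an estimated correlation). arcA, the deiminase, fell by 1.44 ± 0.20, arcB by 1.67 ± 0.12 and arcC1, a carbamate kinase, by 2.38 ± 0.16. This set call ended without aerobic/static array 1 (adjusted p = 0.0602) and without respiratory/aerobic array 2. Of 42 tested genes of other amino acid pathways, among them aromatic, methionine, cysteine, serine, threonine and lysine synthesis, 18 rose and 3 fell, and adjusted over the list alone 17 and 3 (camera adjusted p = 0.0116, adjusted p = 0.589 with an estimated correlation). The set call ended with a set test on all genes tested (adjusted p = 0.0529). Examples were metB1 (1.55 ± 0.17), lysA (1.61 ± 0.21) and trpE (1.03 ± 0.14) of methionine, lysine and tryptophan synthesis. Peptide use rose in 14 of 25 genes and fell in 4, and adjusted over the list alone in 15 and 4 (camera adjusted p = 0.0115, adjusted p = 0.589 with an estimated correlation). The tripeptidase gene pepT rose by 3.45 ± 0.18 and pepN by 1.71 ± 0.15. Of 13 arginine and glutamate genes, 1 rose and 6 fell, and adjusted over the list alone 1 and 4 (camera adjusted p = 0.284). That list passed with fry (adjusted p = 0.0273). glnQ, of a glutamine transporter, fell by 1.97 ± 0.15.

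Purine and pyrimidine genes moved in opposite directions. Of 19 purine genes, 14 fell and 1 rose, also adjusted over the list alone, with a median change of -2.42. The set test held only the 13 members measured on every array, without purC, purD, purM and purQ (camera adjusted p = 0.043, adjusted p = 0.589 with an estimated correlation). Over the genes on both aerobic/static arrays, the list median was -4.04 on the first-set array and -1.12 on the Repl array. The set call ended without aerobic/static array 1 (adjusted p = 0.0708). purC had the lowest fitted change of all genes, -5.04 ± 1.33, from -7.54 on the first-set array and -1.04 on the Repl array. Every purine gene named among the 10 lowest lost its call with a dye term: purC, purD, purF, purH, purM and purQ. The calls of purC, purM and purQ also ended with the own arrays alone, and those of purC, purD, purM and purQ on leaving out single arrays. The salvage genes hprT (-3.46 ± 0.50) and apt (-1.64 ± 0.19) kept their calls with a dye term. Of 15 pyrimidine genes, 11 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0115, adjusted p = 0.589 with an estimated correlation). carA and carB, subunits of carbamoyl phosphate synthase, rose by 1.34 ± 0.22 and 1.65 ± 0.29, and both lost their calls with a dye term. Among the ribonucleotide reductase genes, nrdD and nrdG of the anaerobic enzyme fell by 1.48 ± 0.17 and 1.43 ± 0.21, and nrdF of the aerobic enzyme rose by 1.52 ± 0.20. nrdE changed by 0.28 ± 0.13 (adjusted p = 0.10).

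Translation genes fell in aerobic cultures. Of 53 ribosomal protein genes, 43 fell and 1 rose, and adjusted over the list alone 43 fell and 2 rose, with a median change of -1.51 (camera adjusted p = 9.74e-10, adjusted p = 0.589 with an estimated correlation). rplC fell by 2.23 ± 0.17 and rplB by 1.90 ± 0.14. Of 31 tRNA synthetase and translation factor genes, 15 fell and 5 rose, also adjusted over the list alone (camera adjusted p = 0.0474, adjusted p = 0.589 with an estimated correlation). That call ended under 4 alternatives, quantile normalization among them. infB, the translation initiation factor, fell by 1.38 ± 0.13. In fatty acid synthesis 12 of 17 genes fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0244, adjusted p = 0.589 with an estimated correlation). The member that rose was lplL (2.44 ± 0.31), a lipoate-protein ligase, and accD of acetyl-CoA carboxylase fell by 0.85 ± 0.13. This set call ended with a dye term (adjusted p = 0.0543), with a set test on all genes tested (adjusted p = 0.111) and without aerobic/static array 2 (adjusted p = 0.0752). Of 35 cell envelope genes, 21 fell and 5 rose, and adjusted over the list alone 23 and 6 (camera adjusted p = 0.0115, adjusted p = 0.589 with an estimated correlation). murA1 of peptidoglycan synthesis fell by 1.34 ± 0.14 and murE rose by 1.04 ± 0.14.

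The remaining lists did not pass the camera test in aerobic against static. With fry, which tests against no change, the metal, ATP synthase and competence lists passed (adjusted p = 0.0273, 0.0487 and 0.00928). The chaperone and prophage lists did not pass with fry (adjusted p = 0.0673 and 0.492). Of 18 metal transport genes, 4 rose and 3 fell (camera adjusted p = 0.849), with cadA, a cadmium-transporting ATPase, at -3.79 ± 0.19 and fur, a metal uptake regulator, at 1.18 ± 0.18. Of 18 chaperone and protease genes, 6 rose and 1 fell, and adjusted over the list alone 4 and 1 (camera adjusted p = 0.091). Of 7 ATP synthase genes 3 fell (camera adjusted p = 0.425), of 8 competence genes 3 rose and 1 fell (0.463), and of 76 prophage genes 7 rose and 22 fell, with 6 and 20 adjusted over the list alone (0.378). The counts of the metal, ATP synthase and competence lists were the same adjusted over the list alone. The prophage gene ps312 rose by 3.88 ± 0.20. The largest rises included genes with no assigned function, such as yagE (4.01 ± 0.28) and ymdE (3.99 ± 0.28). The count of 1083 was 569 with a dye term and 469 with a 2-fold minimum.

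Between shaken cultures with hemin and static cultures, some of the largest changes were in the heme efflux operon and in adhE. ygfC, ygfB and ygfA rose by 5.76 ± 0.16 (54.0-fold), 5.72 ± 0.22 and 4.76 ± 0.45 against static cultures. The operon encodes a heme-sensing regulator (ygfC) and an ABC transporter that exports heme. All 3 genes passed, over all genes and adjusted over the list alone, but this series is known for the operon, so the list is not independent evidence. adhE fell by 5.85 ± 0.24 (57.7-fold), as did cadA (-3.85 ± 0.19) and aspB (-3.76 ± 0.22), an aspartate aminotransferase. In all, 698 of 1792 genes passed, 383 higher and 315 lower in respiratory cultures. Of these, 129 were at least 2-fold higher and 101 at least 2-fold lower.

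Some nitrogen genes were among the largest changes in respiratory against static cultures, which differ in both shaking and hemin. The genes glnQ, arcA, arcB and arcC1 also fell in shaken cultures without hemin. glnB, the PII nitrogen regulator, rose by 2.82 ± 0.12 and amtB, an ammonium transporter, by 2.48 ± 0.18, while glnQ fell by 2.96 ± 0.15. As a set, the 13 arginine and glutamate genes did not pass (2 rose and 3 fell, also adjusted over the list alone, camera adjusted p = 0.541). In the arginine deiminase list 5 of 11 genes fell and none rose, also adjusted over the list alone (camera adjusted p = 0.00395, adjusted p = 0.624 with an estimated correlation). The median member changed by -0.19 and the mean by -1.04, since arcA (-2.14 ± 0.20), arcB (-2.13 ± 0.12), arcC1 (-2.39 ± 0.16), arcC2 (-2.75 ± 0.23) and arcD1 (-2.32 ± 0.15) stood apart from the rest. Peptide genes rose in 13 of 25 and fell in 3, also adjusted over the list alone (camera adjusted p = 0.0156, adjusted p = 0.624 with an estimated correlation), with pepT at 2.01 ± 0.18 and oppC, of an oligopeptide transporter, at 0.99 ± 0.12. Among other amino acid genes 18 of 42 rose and 4 fell, and adjusted over the list alone 19 and 4 (camera adjusted p = 0.0432, adjusted p = 0.684 with an estimated correlation). That call ended in 7 of 14 further alternatives, with an adjusted p of 0.108 from the own arrays alone.

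In the respiratory chain list 11 of 17 genes rose and none fell, also adjusted over the list alone, with a median change of 0.56 (camera adjusted p = 0.00125, adjusted p = 0.624 with an estimated correlation). menD (0.89 ± 0.13), menX (0.95 ± 0.14) and hemN (0.97 ± 0.15), an oxygen-independent coproporphyrinogen oxidase homologue, rose. cydA at 0.33 ± 0.15 and cydB at 0.32 ± 0.13 did not pass (adjusted p = 0.11 and 0.082), nor did hemH at 0.19 ± 0.16 (adjusted p = 0.36). Oxidative stress genes rose in 13 of 19 and fell in 1, also adjusted over the list alone, with a median of 0.83 (camera adjusted p = 0.00395, adjusted p = 0.650 with an estimated correlation). osmC rose by 2.22 ± 0.26 and pmsX by 2.03 ± 0.20. sodA rose by 1.23 ± 0.20 and noxE by 0.64 ± 0.15. Both lost their call with a dye term. The call of noxE ended in 7 of 16 alternatives, with 2 sets of shared cultures among them, and its direction turned with quantile normalization (-0.12). Of 18 metal genes, 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.889), and fhuD, of a ferrichrome uptake system, rose by 1.19 ± 0.15.

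Of 21 pyruvate genes, 9 rose and 3 fell, and adjusted over the list alone 11 and 4 (camera adjusted p = 0.131). That list passed with fry (adjusted p = 0.0339). aldC (2.21 ± 0.18), als (2.09 ± 0.22), pdhD (1.92 ± 0.20) and pdhB (2.57 ± 0.27) rose, as did lplL (3.25 ± 0.31). pfl fell by 1.75 ± 0.23, a call lost with a dye term, and ldh at -0.34 ± 0.17 did not pass (adjusted p = 0.14). Glycolysis and PTS genes fell in 8 of 24 and rose in 1, also adjusted over the list alone (camera adjusted p = 0.010, adjusted p = 0.624 with an estimated correlation), with pgk, phosphoglycerate kinase, at -0.82 ± 0.15. This set call ended with a set test on all genes tested (adjusted p = 0.0629). With fry, which tests against no change, the list did not pass either (adjusted p = 0.0607). Of 42 other carbohydrate genes, 7 rose and 11 fell, and adjusted over the list alone 7 and 12 (camera adjusted p = 0.0778).

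Ribosomal protein genes fell in 17 of 53 and rose in 1, also adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.000242, adjusted p = 0.624 with an estimated correlation). With fry, which tests against no change, the ribosomal list did not pass (adjusted p = 0.0607). rpsO rose by 1.06 ± 0.15. rplL fell by 1.06 ± 0.16, a call lost with a dye term. Cell envelope genes fell in 11 of 35 and rose in 2, and adjusted over the list alone 10 and 2 (camera adjusted p = 0.00395, adjusted p = 0.624 with an estimated correlation), with rmlA, of rhamnose synthesis, at -1.24 ± 0.21, a call lost with a dye term. Prophage genes fell in 26 of 76 and rose in 4, also adjusted over the list alone (camera adjusted p = 0.00395, adjusted p = 0.624 with an estimated correlation), with ps312 again higher at 3.36 ± 0.20. With fry the prophage list did not pass either (adjusted p = 0.0895). Pyrimidine genes rose in 5 of 15, 4 when adjusted over the list alone, and none fell (camera adjusted p = 0.041, adjusted p = 0.725 with an estimated correlation). That set call ended in 10 of 14 further alternatives, with an adjusted p of 0.225 with a dye term. Purine genes fell in 10 of 19 and rose in 1, also adjusted over the list alone. The 13 measured on every array did not pass as a set (camera adjusted p = 0.131). The fitted list median was -1.97. On the respiratory/static arrays the list median was -2.999 over 19 genes in the first set and -0.126 over 16 genes in the Repl set. Over the genes measured on both respiratory/static arrays, the list median was -0.723 on the first-set array and -0.126 on the Repl array. The calls of purE, purF, purM and purQ ended with a dye term, with the own arrays alone and on leaving out single arrays. nrdD (-1.40 ± 0.17) and nrdG (-1.24 ± 0.21) fell, and nrdF (1.48 ± 0.20) and nrdE (0.41 ± 0.13) rose. The call of nrdF ended with a dye term, and that of nrdE in 10 of 16 alternatives, with 2 sets of shared cultures among them. In fatty acid synthesis 3 of 17 genes rose, 1 when adjusted over the list alone, and none fell (camera adjusted p = 0.0627). Of 31 translation factor genes 5 rose and 5 fell, with 5 and 4 adjusted over the list alone (0.473). Of 18 chaperone and protease genes 3 rose and 1 fell, with 1 and 0 adjusted over the list alone (0.785). Of 7 ATP synthase genes none passed (0.669). Of 8 competence genes 2 rose and 2 fell, with 4 and 2 adjusted over the list alone (0.669).

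The count of 698 was 133 with a dye term, 316 from the own arrays alone, 246 with 2 sets of shared cultures, 422 from the Repl set alone, 230 with a 2-fold minimum, and 285 without respiratory/static array 1. All alternatives except the other sign for the swapped array kept the calls of ygfA, ygfB, ygfC, adhE, cadA, glnB, glnQ and amtB.

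**Figure D1:**
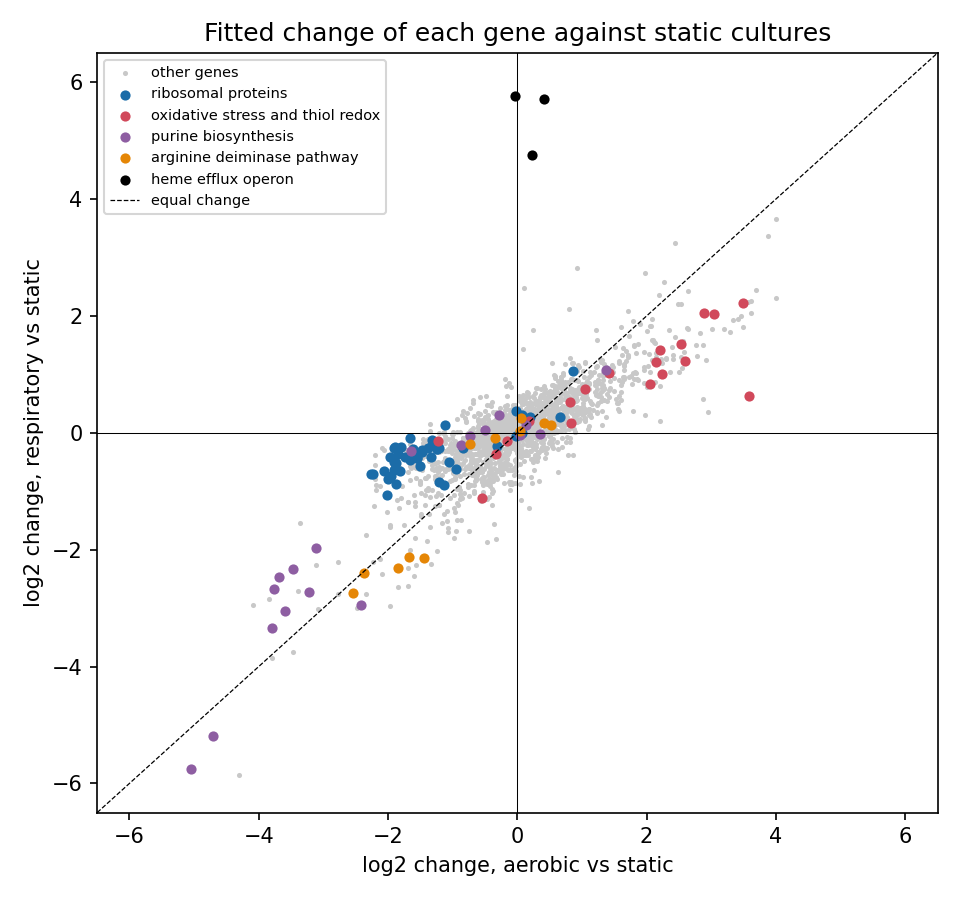
Fitted log2 change of 1792 genes in aerobic against static (horizontal axis) and respiratory against static cultures (vertical axis), 1 point per gene, with 5 gene lists in colour and a dashed line of equal change. The 3 heme efflux genes lie near 0 on the horizontal axis and between 4.76 and 5.76 on the vertical axis, and ribosomal protein genes have medians of -1.51 and -0.36.

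Shaken cultures with hemin had higher expression of the heme efflux operon, translation and fatty acid genes and lower expression of oxygen defence genes than shaken cultures without it. The set calls of the translation, fatty acid and oxidative stress lists were lost with an estimated correlation (adjusted p = 0.691 with an estimated correlation), and the heme efflux operon was too short for a set test. ygfC rose by 5.79 ± 0.16 (55.5-fold), ygfB by 5.31 ± 0.22 and ygfA by 4.52 ± 0.45, all 3 also adjusted over the list alone, which is not independent evidence. noxE fell by 2.95 ± 0.15 (7.72-fold) and sodA by 1.36 ± 0.20. amtB rose by 2.37 ± 0.18 and glnB by 1.89 ± 0.12. Of 1792 genes, 640 passed, 378 higher and 262 lower with hemin, of which 99 were at least 2-fold higher and 63 at least 2-fold lower.

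Ribosomal protein genes rose in 39 of 53, 40 when adjusted over the list alone, and none fell, with a median change of 1.13 (camera adjusted p = 7.86e-12, adjusted p = 0.691 with an estimated correlation). rpsJ rose by 1.65 ± 0.16 and rplW by 1.48 ± 0.13. Translation factor and tRNA synthetase genes rose in 14 of 31 and none fell, with 14 and 1 adjusted over the list alone (camera adjusted p = 0.0226, adjusted p = 0.691 with an estimated correlation). The call of that list ended with 2 sets of shared cultures (adjusted p = 0.0539). Fatty acid genes rose in 13 of 17, 15 when adjusted over the list alone, with a median of 1.06 (camera adjusted p = 2.16e-05, adjusted p = 0.691 with an estimated correlation). accA (1.16 ± 0.17), accC (1.20 ± 0.16) and accD (1.15 ± 0.13) of acetyl-CoA carboxylase rose together with fabG1 (1.11 ± 0.16), a ketoacyl-carrier protein reductase. Of 7 ATP synthase genes 3 rose, also adjusted over the list alone (camera adjusted p = 0.242), with atpH at 1.01 ± 0.12. That list passed with fry (adjusted p = 0.0460). Of 35 cell envelope genes 7 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.27).

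Oxidative stress genes fell in 11 of 19 and rose in 1, with 12 and 1 adjusted over the list alone and a median of -0.79 (camera adjusted p = 6.47e-05, adjusted p = 0.691 with an estimated correlation). ahpF of alkyl hydroperoxide reductase fell by 1.22 ± 0.20, and noxD, annotated as an NADH oxidase, rose by 1.08 ± 0.16. In the respiratory chain list 3 of 17 genes rose, 0 when adjusted over the list alone (camera adjusted p = 0.469). noxB, cydC and cydD were these 3, at 0.56 ± 0.14, 0.49 ± 0.14 and 0.55 ± 0.16, and each lost its call when only the own arrays were used, with calls ended in 3, 7 and 6 of 16 alternatives. Of 18 metal genes 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.726).

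Among fermentation genes, adhE fell by a further 1.54 ± 0.24. Of 21 pyruvate genes 2 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.242). Of 24 glycolysis and PTS genes 3 rose, 2 when adjusted over the list alone (camera adjusted p = 0.986), with ptnAB at 1.46 ± 0.19 and ptnC at 1.56 ± 0.22. Of 42 other carbohydrate genes 8 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.968). llrG and kinG, a response regulator and a histidine kinase, rose by 1.82 ± 0.15 and 1.77 ± 0.17. The genes mycA, of a family of fatty acid hydratases, and fadA, an acetyl-CoA acyltransferase, fell by 2.59 ± 0.24 and 2.00 ± 0.18. Of 13 arginine and glutamate genes 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.437). That list passed with fry (adjusted p = 0.0256). In the arginine deiminase list 1 of 11 genes rose and 3 fell, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.27). The gene arcA was among those that fell, and its call ended in 6 of 16 alternatives. Among other amino acid genes 5 of 42 rose and 9 fell, and among peptide genes 4 of 25 rose and 6 fell, both also adjusted over the list alone (camera adjusted p = 0.242 and 0.158). pepT fell by 1.45 ± 0.18.

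Purine genes rose in 5 of 19, 4 when adjusted over the list alone, and none fell (camera adjusted p = 0.139 over 13 members), with apt at 1.32 ± 0.19. Pyrimidine genes fell in 3 of 15, 1 when adjusted over the list alone, and none rose (0.0839). Prophage genes fell in 12 of 76 and rose in 4, with 7 and 1 adjusted over the list alone (0.0839). Chaperone and protease genes fell in 2 of 18 and rose in 1, with none adjusted over the list alone (0.0839). Of 8 competence genes 1 rose and 2 fell, with 1 and 3 adjusted over the list alone (0.437). None of 4 ribonucleotide reductase genes passed. Of 3 transposase genes, 1 rose and 2 fell here, 1 rose and 1 fell in aerobic against static, and none passed in respiratory against static, with the same counts adjusted over the list alone. The median, mean and set test of a list differed in sign for the competence genes in both comparisons with static and for the glycolysis and PTS genes here. The count of 640 was 281 from the own arrays alone, 162 with a 2-fold minimum and 314 without respiratory/aerobic array 2. With the swapped array left unturned 0 genes passed in limma, as turning decides whether both arrays of this comparison add or cancel.

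**Figure D2:**
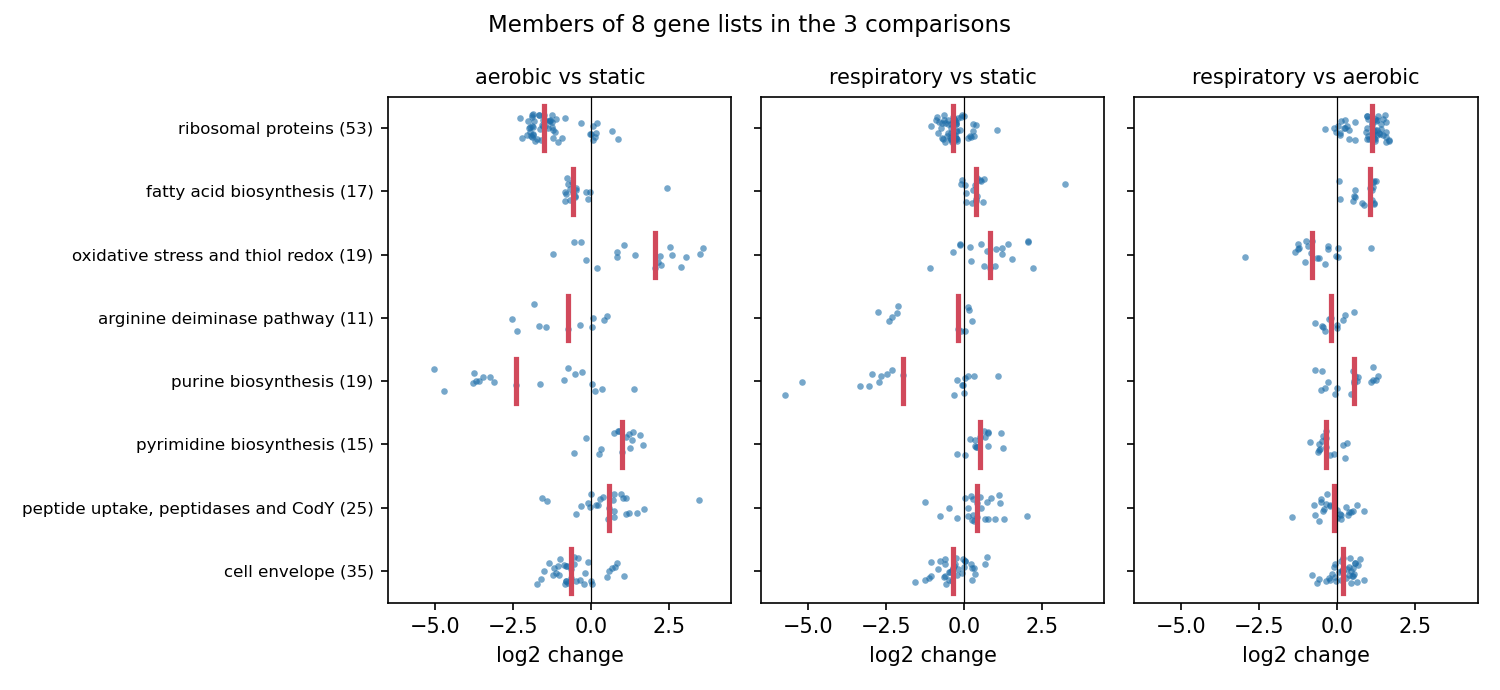
Fitted log2 change of each tested member (blue points) of 8 gene lists in the 3 comparisons, with the number of members in parentheses and the list median as a red bar. Ribosomal protein medians were -1.51, -0.36 and 1.13, and oxidative stress medians were 2.05, 0.83 and -0.79, from left to right.

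**Figure D3:**
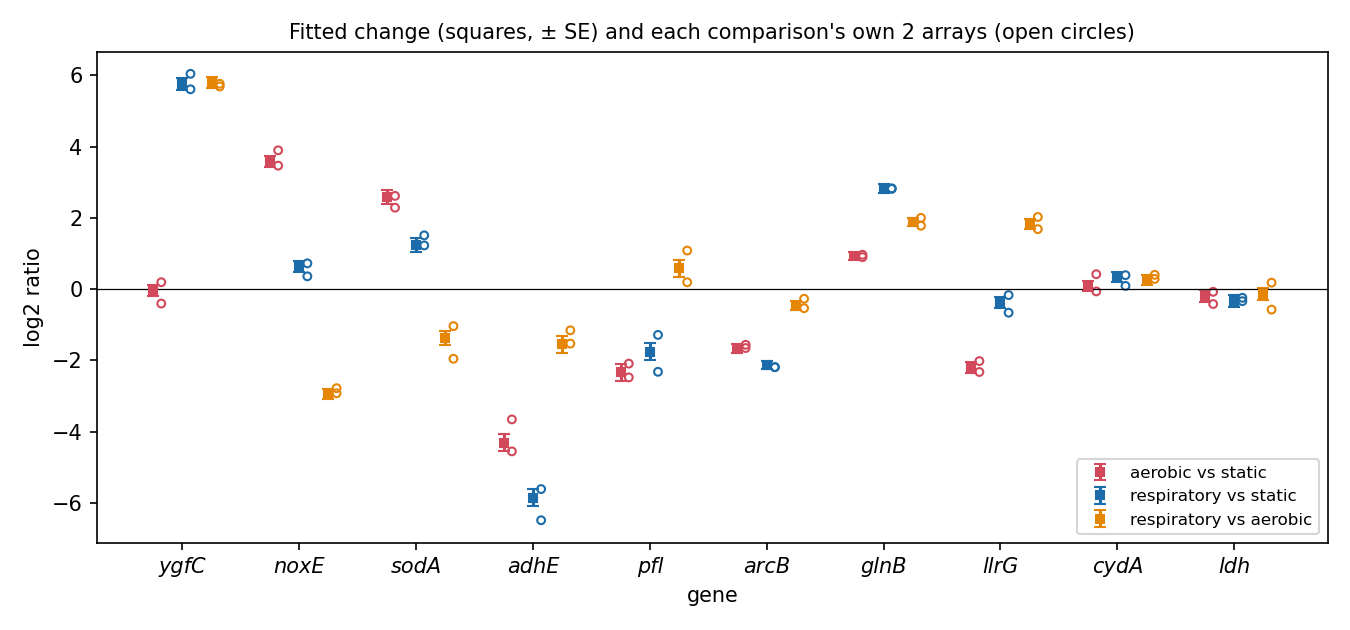
Fitted log2 change with its standard error (squares) and the values of each comparison's own 2 arrays (open circles) for 10 genes, coloured by comparison. noxE was at 3.58 in aerobic against static and at -2.95 in respiratory against aerobic cultures, and cydA and ldh did not pass in any comparison.

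The changes of both shaken conditions against static were compared across genes. Their Pearson correlation was 0.80 and their Spearman correlation 0.81, beside 0.50 and 0.48 in simulations with no effect. The simulated correlation arises because every array enters both fitted effects. Simulated arrays were independent, so deviations shared through static cultures or by the arrays of a set were left out of these values. The covariance was 0.688 against 0.0196 simulated, a difference of 0.669. Arrays of different sets correlated at 0.65 and 0.70. Genes higher in both numbered 310, beside 109.9 for independent lists of these sizes, and genes lower in both 250, beside 100. No gene was higher in aerobic and lower in respiratory cultures, and 3 were lower in aerobic and higher in respiratory cultures. Part of the excess may come from the shared static cultures. A gene-specific dye bias may also add to it, since the test condition carried Cy5 on every aerobic/static and respiratory/static array. Such a bias would enter both effects with the same sign, also between arrays of different sets. Of the genes that rose in aerobic cultures, 198 were lower in respiratory than in aerobic cultures and 4 were higher. Of those that fell in aerobic cultures, 308 were higher in respiratory than in aerobic cultures and 12 were lower. Independent lists of these sizes would share 75.1, 108.4, 120.0 and 83.2 genes, in the same order. Both estimates hold the aerobic cultures with opposite sign, so opposite calls arise in part without any effect. Independence therefore does not hold for this pair, and no p-value was computed for its overlap.

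In limma 0 of 1792 genes passed the test of loop closure, with 6 (0.335%) at an unadjusted p under 0.05 and a smallest adjusted p of 1.00. That is fewer than the 5% that chance alone gives with independent arrays. Deviations shared by the arrays of a set can cancel in the loop and widen the residual, so this test may have had little power to find a loop that does not close. Its power was not measured. In the test of a dye effect 0 genes passed, with 196 (10.9%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.20. That share is more than the 5% that chance alone gives.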

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

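Among the 309 genes left untested for blank values, some had both arrays of a comparison at least 2-fold away from 0 in the same direction. There were 8 in aerobic against static, of 37 measured on both arrays, and all were lower: pi133, rgpC, yafJ, ycaG, ymcA, yxbD, yxbE and yxbF, the last with a mean of -3.36 (SD 0.26). In respiratory against static there were 4 of 5, all lower: yafJ (-2.18), yxbD (-3.63, SD 1.71), yxbE (-4.42, SD 0.25) and yxbF (-4.67, SD 0.85). In respiratory against aerobic there were 2 of 28, both lower: ybdI (-1.68) and ybeF (-1.35). No test was made for these genes. For scale, 469 of 1792 tested genes passed with at least a 2-fold fitted change in aerobic against static, 229 higher and 240 lower. The untested genes were set apart by blanks, whose reason is not given. Whether blanks favoured genes with lower ratios was not tested.

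Purine synthesis genes were further below 0 on the first-set aerobic/static array than on the Repl array, with medians of -4.04 and -1.12 over the genes on both, a ratio of 0.278. Compression of the whole Repl array was excluded as the whole cause, since other genes had a slope of 0.766 (95% interval 0.737 to 0.794). The intervals in this paragraph came from 2000 resamples of genes. Genes are not independent replicates, so the intervals may be too narrow and do not cover the spread between arrays or cultures. Compression of strong falls alone could not be decided, because only 10 other genes fell that far, with a median ratio of 0.817 (0.330 to 1.07). A difference between the static cultures of the 2 sets could not be decided either: the median differences between sets were -0.008 on the respiratory/aerobic, -1.998 on the aerobic/static and -0.896 on the respiratory/static arrays, and the interval of the deciding difference, -1.12 to 0.273, included 0. No biological explanation was tested, as no label separates the sets, and all tests in this part were chosen only after the results were seen.

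Arrays of a set deviated together across 1651 genes. The differences between sets correlated at 0.507 for aerobic/static with respiratory/static, 0.251 for respiratory/static with respiratory/aerobic and 0.186 for aerobic/static with respiratory/aerobic. Shared cultures within a set need the last value to be below 0, so they cannot be the whole cause. A gene-specific dye bias that differed between sets needs the last 2 values to have the same sign, as they did, and their gap was 0.0649. The tests leave this dye bias open and cannot tell it from a difference in spread between the sets. The standard deviation across genes was 1.22 on the first-set and 0.97 on the Repl aerobic/static array. It was 0.99 and 0.77 on respiratory/static, and 0.63 and 0.79 on respiratory/aerobic arrays. Real changes measured at unlike spread also enter the differences between sets. No biological explanation was tested.

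Changes with hemin ran against changes with shaking in most genes that passed both tests, such as the ribosomal protein genes. Chance values of shared arrays were excluded as the whole cause, because arrays of different sets correlated at -0.597 and -0.548 (aerobic/static with respiratory/aerobic). A gene-specific dye bias would make the pair of arrays with the same dye orientation correlate above 0, and that pair had the value -0.548. Ribosomal protein medians were -1.23 and -1.65 on the aerobic/static arrays and 1.05 and 1.27 on the turned respiratory/aerobic arrays. Aerobic cultures used by both sets, and a trend with intensity in the authors' normalization, were not tested, so an effect of hemin itself remains a hypothesis beside them.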

How the results depend on the processing

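Where a value changed with the processing, the cause was not tested. With a gene-specific dye term, 569 genes passed in aerobic against static (275 higher, 294 lower) and 133 in respiratory against static (92, 41). Own arrays alone left 316 (191, 125) in respiratory against static and 281 (198, 83) in respiratory against aerobic. With 2 sets of shared cultures respiratory against static had 246 (152, 94), and with only the Repl set 422 (230, 192). A 2-fold minimum left 469, 230 and 162 in the 3 comparisons. With the other sign for the swapped array the counts were 259 (169, 90), 316 and 0. Centring, equal spread, quantile normalization, robust eBayes and only genes on all 6 arrays kept each count within 1.5 times. Leaving out each array in turn gave 883 to 1043, 285 to 730 and 314 to 553 genes. The correlation of both effects against static was 0.78 from own arrays, 0.65 and 0.70 from arrays of different sets, and 0.77 to 0.83 leaving out each array. Of 25 set calls, 0 passed with an estimated correlation, a test that rests on 4 residual degrees of freedom, and 13 were kept in all 14 other alternatives. With fry there were 31 set calls, with 10 gained and 4 lost. Loop closure and dye effect had 0 genes in every alternative run. Direction was reversed for noxE in respiratory against static with quantile normalization (-0.12), and, in respiratory against aerobic with the other sign for the swapped array, for yhjA (0.20), cydC (-0.0193), cydD (-0.11), aldR (0.0743) and arcA (0.0173). Leaving out all alternatives on sign and fold, 76 of 99 named calls in aerobic against static were kept throughout, 40 of 95 in respiratory against static and 56 of 90 in respiratory against aerobic. The alternative with rows kept separate gives no value, since no gene has more than 1 row. The titles pair arrays only by a suffix, and the fit with 2 sets of shared cultures, which treats the sets as paired, gave 940, 246 and 582 genes. Signal over background was not examined, as the table holds no intensities.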

Other observations

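Groups of genes outside the lists were formed by shared symbol prefix, a rule chosen after seeing the data, and no set test was made for them. A group was kept only where, in some comparison, at least 3 members passed in the same direction and none in the other. Uniform directions were thus selected by outcome. Of all genes tested, 60.4% passed in aerobic against static, 39.0% in respiratory against static and 35.7% in respiratory against aerobic. All 4 glycogen genes (glgA, glgC, glgD, glgP) rose in aerobic against static (median 2.05) and in respiratory against static (1.30), and 2 fell when hemin was added (-0.74). All 4 spermidine and putrescine transport genes (potA to potD) fell in aerobic against static (-1.67), none passed in respiratory against static (-0.24), and 4 rose when hemin was added (1.45). The 4 plp genes, annotated as lipoproteins, fell in both comparisons with static (-1.68 and -0.72) and rose with hemin (0.98). Of 6 histidine kinase genes (kinB to kinG), 4 fell in aerobic against static (-1.15) and 2 in respiratory against static (-0.14), and 3 rose with hemin (0.60). The 3 nif genes fell in aerobic against static (-1.57), 2 fell in respiratory against static (-0.52), and 3 rose with hemin (1.00).

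Nucleotide excision repair genes uvrA, uvrB and uvrC rose in aerobic against static (median 0.73), 2 rose in respiratory against static (0.57), and none passed when hemin was added. Of 6 phosphate transport genes (pstA to pstF), 3 rose and 1 fell in aerobic against static, 4 rose in respiratory against static, and 1 rose with hemin. Of 9 dna genes of replication, 3 fell in aerobic against static, 1 rose in respiratory against static and 4 rose with hemin. Of 8 cell division genes (fts), 1 rose and 4 fell, 1 rose and 1 fell, and 4 rose, in the same order. Of 6 recombination genes (rec), 3 fell, none passed, and 2 rose.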
